A study of Mus musculus with 8 samples.

How the data were processed

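Live stromal cells of the mouse large intestine (podoplanin-positive cells without CD45, CD31, EpCAM or 7AAD signal) were sorted from 8 mice aged 12 weeks and profiled by RNA-seq from full-length SMART-Seq cDNA, per the labels' protocols and the series' design text. The 4 control libraries came from mice with floxed Il10ra alleles and the 4 cKO libraries from mice with the same alleles and a Pdgfra-driven Cre recombinase. Groups and replicate numbers were taken from the genotype labels and titles, and each library is a separate mouse, per the series' design text.

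The authors deposited 1 table of FPKM values (fragments scaled by transcript length and by the mapped fragments of the library) for each library, with 24346 gene symbols in the same order. The submitters' processing notes name the mm10 build, TopHat2 2.1.1, Bowtie2 2.3.5.1, SAMtools 0.1.18, Cuffdiff and Cufflinks 2.2.1. Alignment settings, the gene annotation and any further scaling are not given in the sources used here. FPKM divides by gene length and by the fragments of the whole library, so that genes that take a larger share lower the values of all others, and a very short gene reaches a high FPKM from a single fragment. Genes with near-identical copies share fragments, and these values were treated as uncertain. Gene positions are those of the GENCODE annotation of the same build (GRCm38). Of the symbols, 23143 matched the RefSeq gene table, which was used for gene types and chromosomes.

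Fragment counts were not analysed here, and a count model was therefore not used. Depth was read from the low values. Over genes with a mean FPKM under 0.3, ratios between libraries lay on the same few whole-number steps (tolerance 0.002 on the log2 scale) for 57.9% to 65.3% of the genes compared, against 1.04% to 1.19% at random offsets. These steps gave relative depths of 0.859 to 1.08 between libraries. From 82 genes with a single annotated transcript of at least 4000 bp, the depth was put at a median of 17800000 fragments, with quartiles of 16300000 and 17900000. Because not all values lay on whole steps, fragments are given for Il10ra and Mir5098 only.

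The test, the filter, the gene lists, the rule for named genes and all alternatives except those named below as added were fixed before the data were examined. Values were transformed to log2(FPKM + 1), and genes with a mean FPKM of at least 1 over all 8 libraries (11506 genes) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, 1 factor with 2 groups). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the 30 lists with at least 3 tested members of the 34 lists fixed), with camera and an estimated correlation, with fry, and by a two-sided exact permutation test of the list mean per library. With 4 against 4 libraries there are 70 arrangements, and the smallest two-sided exact p is 0.0286. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for depth and plots.

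The lists covered interferon responses, antigen presentation, cytokines, extracellular matrix, fibroblast subtypes, crypt niche factors, other cell types that the sort could let through, tissue dissociation and housekeeping functions. Named genes were Il10ra, Il10rb and Pdgfra, the 10 called genes with the highest and lowest fold change among those whose groups did not overlap (filled by smallest unadjusted p where fewer passed), up to 6 called members of each list or else the 3 with the smallest unadjusted p, and the 3 most abundant markers of each cell type. Predicted and small RNA genes were counted but not named by this rule. Genes outside the rule were named after their values were seen: Mir5098, Rest, Gbp8, Gm1987, AF357425, Clca1, Retnlb, Fcgbp, Lyve1, Flt4, Mmrn1, Stab2, Cldn5, Prox1, Reln, Tie1, Ifnb1, Ifng, Cxcl9, Cxcl10 and the Y-linked genes.

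The procedure was tested on simulated data made from the means and spreads of these 11506 genes, in 10 runs. It called 62.4% of genes with a simulated log2 change of 0.5, 94.6% at 1 and 98.5% at 2, and 82 of 112522 unchanged genes. Over all runs 670, 670 and 660 genes were shifted by these amounts. So many changed genes loosen the adjusted threshold. The shares are therefore not the power in the real libraries, where 1 gene was called. A list shifted by 0.15 was called in 10 of 10 runs, with 2 calls of other lists in all runs. Genes in that simulation varied independently, which camera's preset correlation comes close to, whereas list members in the real libraries varied together.

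Alternatives were other pseudocounts (0.1 and 0.25), no filter or a minimum mean FPKM of 5, quantile normalization, median-of-ratios scaling, rescaling to a fixed sum, eBayes without the trend or with robust estimation, array weights, the replicate number as a block, other thresholds, other set tests and each library left out in turn. Leaving out small RNA genes, the mean of the epithelium list as a covariate and the exact permutation test across lists were added after the data were seen. Differences between groups were also compared with those of all 35 divisions of the 8 libraries into 4 and 4.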

Results

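RNA was sequenced from sorted stromal cells of the large intestine of 8 mice aged 12 weeks. In 4 mice the Il10ra gene, which encodes the ligand-binding chain of the interleukin-10 receptor, carried floxed alleles (control). In 4 mice with the same alleles a Cre recombinase driven by Pdgfra, a gene of intestinal fibroblasts, was added (cKO). The series' title names the question as the effect of this receptor in fibroblasts on type I interferon signalling and intestinal pathology. Between 15815 and 16323 genes had an FPKM above 0 in a library, and 11273 to 11804 reached an FPKM of 1. Relative depth ran from 0.859 in control replicate 2 to 1.08 in cKO replicate 3, at an estimated 17800000 fragments per library. Where a gene is given with a pair of values, they are the mean FPKM ± SD of the 4 control and of the 4 cKO libraries, in that order. Correlations of log2 values between libraries ranged from 0.965 to 0.989, so that no library was a copy of another.

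Il10ra (chromosome 9, 45253837 to 45269149, mm10, minus strand) was low in both groups. Its FPKM was 0.842, 0.665, 0.614 and 0.403 in control replicates 1 to 4 and 0.439, 0.273, 0.633 and 0.636 in cKO replicates 1 to 4. On the scale of single fragments these values stood for 149 fragments in the control libraries and 126 in the cKO libraries (each within 0.00065 of a whole number). The group means were 0.631 ± 0.181 and 0.495 ± 0.175 (SD, n = 4 each; two-sided exact permutation p = 0.4). In limma without a filter on low values, the log2 difference was -0.13 (SE 0.11, adjusted p = 0.925), and with a pseudocount of 0.1 in place of 1 it was -0.31 (adjusted p = 0.928). The value sums fragments over the whole gene and the labels do not name the floxed part, so it does not check the genotype labels. Leukocyte transcripts were also measured in these libraries (Lyz2 at 37.7 ± 7.78 and 46.6 ± 20.1). Whether the Il10ra fragments came from fibroblasts or from other cells was not tested. The partner chain Il10rb had an FPKM of 43.5 ± 2.44 in control and 40.4 ± 1.94 in cKO libraries, and the Cre driver gene Pdgfra 158 ± 1.91 and 155 ± 19.0. Neither differed in limma (adjusted p = 0.897 and 0.98). Xist had an FPKM of 5.30 ± 0.170 in control and 6.08 ± 0.769 in cKO libraries, and Ddx3y, Uty, Kdm5d and Eif2s3y, which are Y-linked, were listed at 0 in all 8 libraries.

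Genes of interferon responses and antigen presentation had higher list means in the cKO stromal cells, by of 0.18 to 0.31 on the log2 scale. All 19 tested members of the class I antigen presentation list, 22 of 24 members of the interferon-gamma and class II list and 49 of 55 members of the type I interferon list had a higher mean in cKO. Among them were B2m, the light chain of class I molecules (881 ± 72.9 FPKM in control and 1162 ± 127 in cKO, SD, n = 4 each), Igtp, an interferon-inducible GTPase (14.1 ± 0.863 and 23.8 ± 5.43), and Usp18, an interferon-induced protease that dampens the type I receptor (7.01 ± 0.628 and 10.2 ± 1.45). No single member passed in limma over all 11506 genes. All 3 lists passed with camera at its preset correlation, and none did with an estimated correlation (adjusted p = 0.249 to 0.296). Epithelium, myeloid, smooth muscle and blood endothelium lists were also higher in the cKO libraries by camera at its preset correlation, and none passed with an estimated correlation (adjusted p = 0.294 to 0.786).

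The class I list rose by a mean of 0.29 and a median of 0.26 (camera adjusted p = 6.1e-13; adjusted p = 0.249 with an estimated correlation). Of its members, 9 were higher adjusted over the list alone and 0 over all genes, where limma gave 9 at an unadjusted p under 0.05. H2-T22, a non-classical class I gene (chromosome 17, 36037128 to 36042747), had an FPKM of 6.09 ± 0.680 in control and 8.56 ± 0.585 in cKO, with a log2 difference of 0.43 (SE 0.08, adjusted p = 0.628). H2-Q4 had 2.31 ± 0.400 and 3.70 ± 0.501, and Psmb9, a subunit of the immunoproteasome, 14.4 ± 2.41 and 20.0 ± 1.41. Values of H2-T and H2-Q genes are uncertain because near-identical copies share fragments. For B2m (chromosome 2, 122147686 to 122153083) the log2 difference was 0.40 (SE 0.09, adjusted p = 0.761), with the 4 cKO values above the 4 control values.

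The interferon-gamma and class II list rose by a mean of 0.31 and a median of 0.24 (camera adjusted p = 3.3e-11; adjusted p = 0.294 with an estimated correlation). Of its members, 7 were higher adjusted over the list alone and 0 over all genes, with 10 at an unadjusted p under 0.05 in limma. Igtp (chromosome 11, 58199556 to 58207591) differed by 0.69 (SE 0.15, adjusted p = 0.761). Tgtp2, another GTPase of the same family, differed by 1.07 (SE 0.26, adjusted p = 0.897), and the guanylate-binding protein gene Gbp9 by 0.39 (SE 0.09, adjusted p = 0.897). The value of Tgtp2 is uncertain because its near-identical copy Tgtp1 shares fragments. In cKO replicate 1 Igtp was at 16.1 and Tgtp2 at 1.88, against 24.2 to 28.1 and 4.91 to 6.22 in the other cKO libraries. Without cKO replicate 1, limma called 4 genes in place of 1, namely Mir5098 and the GTPase genes Igtp (log2 difference 0.86, adjusted p = 0.00517), Tgtp2 (1.35, adjusted p = 0.0166) and Gbp8.

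The type I interferon list rose by a mean of 0.18 and a median of 0.14 (camera adjusted p = 6.1e-13; adjusted p = 0.296 with an estimated correlation). Of its members, 0 passed adjusted over the list alone and 0 over all genes, and limma gave 13 higher and 1 lower at an unadjusted p under 0.05. Usp18 (chromosome 6, 121245906 to 121270917) differed by 0.48 (SE 0.10, adjusted p = 0.761), the antiviral gene Rsad2 by 0.59 (SE 0.16, adjusted p = 0.897) and Ifi47 by 0.74 (SE 0.20, adjusted p = 0.897). The list mean per library was 3.65 ± 0.0811 in control and 3.83 ± 0.124 in cKO (SD, n = 4 each; two-sided exact permutation p = 0.0571), and cKO replicate 1 at 3.71 lay below control replicate 1 at 3.74. For the class I list the means were 5.20 ± 0.107 and 5.49 ± 0.142 and for the interferon-gamma list 3.99 ± 0.111 and 4.31 ± 0.168, each with all cKO libraries above all control libraries (exact permutation p = 0.0286 each, the smallest possible, and 0.214 after adjustment over the lists).

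**Figure D1:**
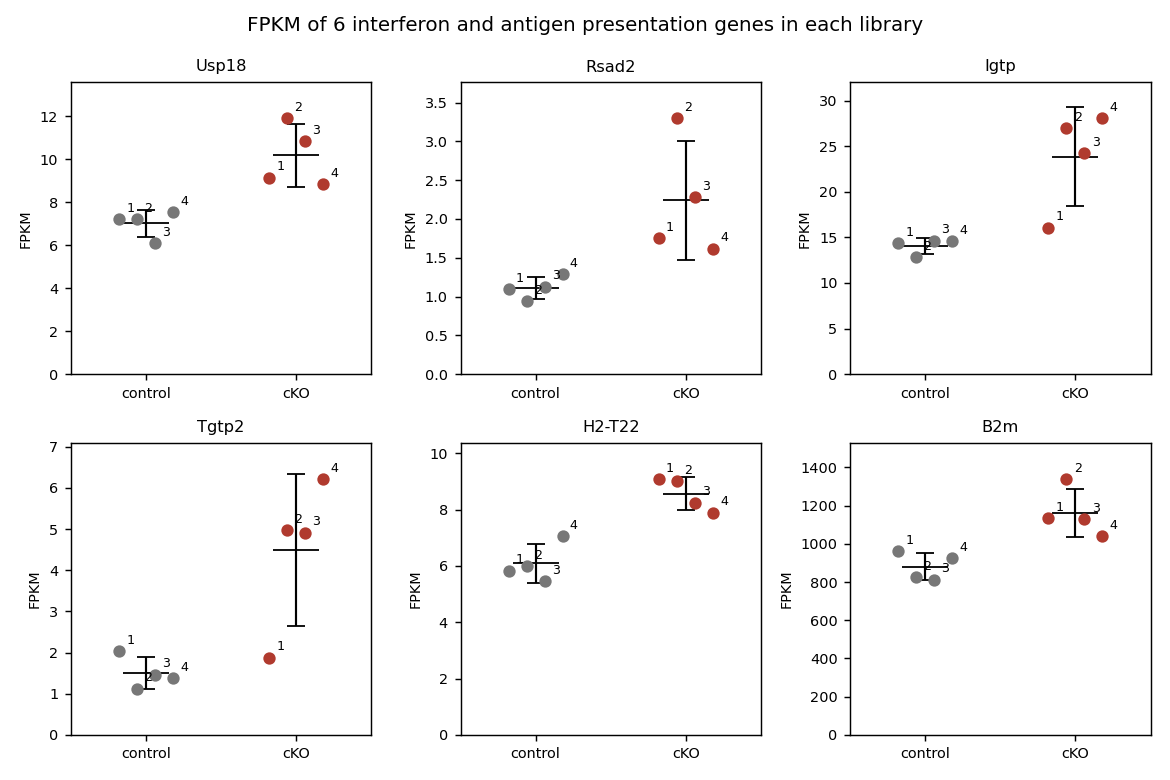
FPKM (vertical axis) of Usp18, Rsad2, Igtp, Tgtp2, H2-T22 and B2m in the 4 control and 4 cKO libraries; points are single libraries with their replicate number, horizontal bars the group mean and whiskers 1 SD. For Tgtp2, cKO replicate 1 at 1.88 lies among the control libraries and the other cKO libraries at 4.91 to 6.22.

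Genes of interferon production and receptors did not pass as a list (17 tested, mean -0.01, camera adjusted p = 0.874). Myd88, an adaptor of Toll-like receptors, had an FPKM of 106 ± 17.7 in control and 89.0 ± 5.56 in cKO, the kinase gene Jak1 111 ± 6.43 and 104 ± 4.01, and Irf5 6.28 ± 0.756 and 7.07 ± 0.746. The IL-10 family receptor list did not pass (8 tested, mean -0.04, camera adjusted p = 0.269). Il20rb was at 1.12 ± 0.290 and 1.60 ± 0.296 and Sbno2 at 36.9 ± 5.95 and 30.1 ± 6.57. The adjusted p of that list was 0.0322 without cKO replicate 1, 0.0226 with a minimum mean FPKM of 5 and 0.0247 with the epithelium list mean as a covariate. The list of inflammatory cytokines and chemokines did not pass either (28 tested, mean -0.01, median 0.00, adjusted p = 0.874). In it the monocyte attractant Ccl2 had 927 ± 154 and 723 ± 241, Ccl8 55.9 ± 9.77 and 47.9 ± 6.46, and Tslp 7.07 ± 0.685 and 8.14 ± 0.823.

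Cytosolic ribosomal protein genes were lower in cKO, all 30 in the mean, with a list mean change of -0.13 and a median of -0.14 (camera adjusted p = 1.4e-17; adjusted p = 0.296 with an estimated correlation). In limma 0 members passed over the list alone or over all genes and 17 had an unadjusted p under 0.05. Rps2 had an FPKM of 825 ± 31.2 in control and 736 ± 23.4 in cKO, Rps9 544 ± 8.84 and 480 ± 31.0, and Rps18 923 ± 21.0 and 822 ± 41.2. The list means were 8.65 ± 0.0178 and 8.52 ± 0.0943 (SD, n = 4 each; exact permutation p = 0.0286), and the mean change was -0.07 with quantile normalization. With that setting or with rescaling to a fixed sum, 1 of the 30 genes was higher in cKO.

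Markers of CD81- or Pi16-positive adventitial fibroblasts fell by a mean of 0.105 as a list, with 20 of 24 members lower in the mean (camera adjusted p = 3.2e-05; adjusted p = 0.294 with an estimated correlation). Pi16 (chromosome 17, 29317680 to 29330593) had an FPKM of 631 ± 64.4 in control and 501 ± 74.6 in cKO, the protease gene Dpp4 41.8 ± 3.70 and 33.4 ± 3.77, and Ackr4, a scavenger of chemokines, 250 ± 5.95 and 215 ± 24.4. Of the members, 0 passed over the list alone and 0 over all genes in limma, with 6 at an unadjusted p under 0.05, and the list lost its call with quantile normalization (adjusted p = 0.178). There the mean change was -0.06 with 8 of 24 members higher, and with rescaling to a fixed sum it was -0.07 with 7 higher. Markers of PDGFRA-high subepithelial fibroblasts did not pass (22 tested, mean and median -0.02, camera direction higher, adjusted p = 0.955). Wnt5b was at 13.3 ± 1.94 and 15.9 ± 1.68, Dmkn at 8.99 ± 2.84 and 6.24 ± 3.79 and Gli1 at 5.46 ± 0.116 and 5.94 ± 0.381. Markers of lamina propria fibroblasts had a mean change of 0.13, a median of -0.03 and a lower camera direction (21 tested, adjusted p = 0.992). Of these, 1 was higher adjusted over the list alone, Ccl21a (log2 difference 2.48), and the mean of the list rests largely on it. The value of Ccl21a taken singly is uncertain because it shares fragments with a copy, as given below. The members C7 and Fabp4 had 46.8 ± 4.89 and 39.8 ± 4.66, and 3.37 ± 1.17 and 5.92 ± 2.70. Crypt niche factors did not pass (33 tested, mean 0.02, median -0.02, camera direction higher, adjusted p = 0.992). The BMP antagonist Grem1 was at 7.81 ± 1.86 and 5.67 ± 0.764 and Chrd at 25.5 ± 0.872 and 23.05 ± 1.67.

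**Figure D2:**
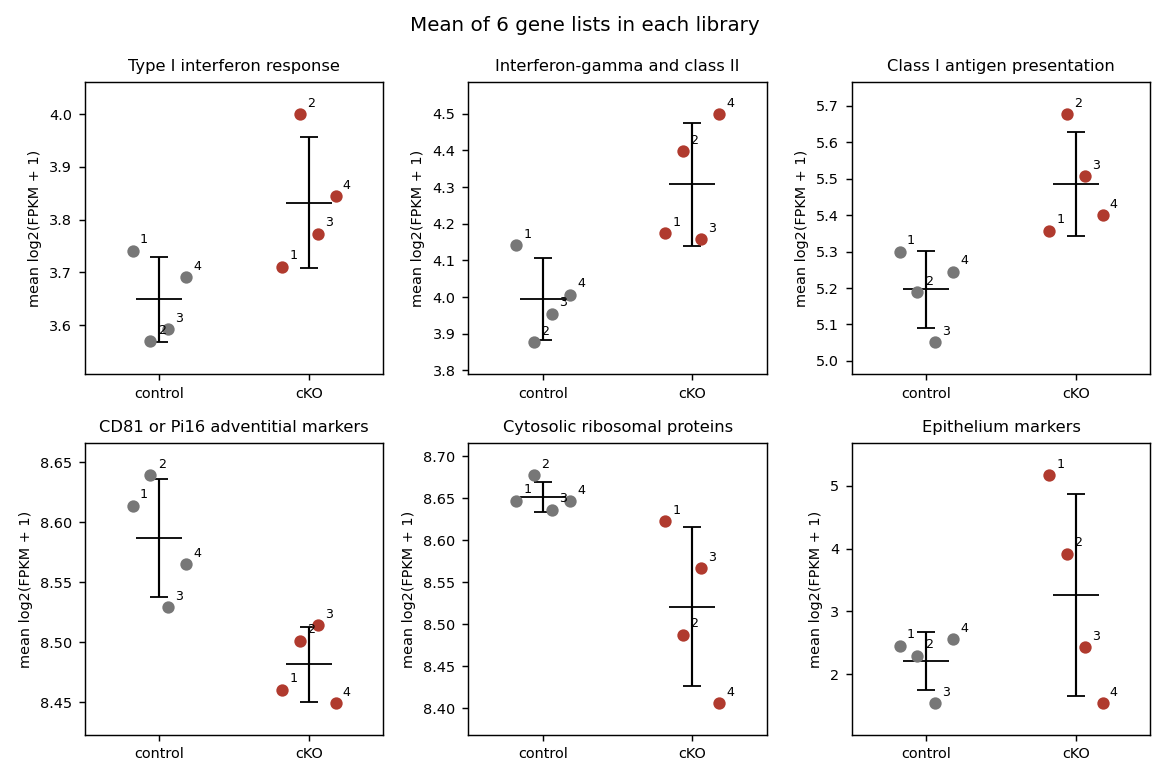
Mean log2(FPKM + 1) (vertical axis, scaled to each panel) of 6 gene lists in the 4 control and 4 cKO libraries; points are single libraries with their replicate number, horizontal bars the group mean and whiskers 1 SD. The class I means are 5.20 ± 0.107 and 5.49 ± 0.142, the ribosomal protein means 8.65 ± 0.0178 and 8.52 ± 0.0943, and the epithelium list reaches 5.17 in cKO replicate 1.

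A further 4 lists fell by less than 0.1 in the mean. The NF-kB and inflammatory fibroblast list (26 tested, mean -0.08, camera adjusted p = 0.00115; adjusted p = 0.560 with an estimated correlation) fell by that test. It held Tnfrsf1b, a receptor of tumour necrosis factor, at 18.4 ± 0.931 and 15.7 ± 1.03, Nfkbia at 910 ± 58.7 and 817 ± 54.6, and Relb at 25.03 ± 2.06 and 21.6 ± 3.20. It lost its call without control replicate 2 (adjusted p = 0.0578) or cKO replicate 2 (0.0929). Its mean change was -0.05 without control replicate 1, -0.04 without control replicate 2, -0.05 without cKO replicate 2 and -0.12 without cKO replicate 1. With rescaling to a fixed sum it was -0.04. The matrix protease and crosslinker list (30 tested, mean -0.08, adjusted p = 0.00265; adjusted p = 0.335 with an estimated correlation) fell by that test. It held the lysyl oxidase gene Loxl2 at 88.1 ± 6.15 and 69.9 ± 10.5, Loxl3 at 28.9 ± 0.439 and 26.6 ± 2.32 and the protease inhibitor Timp2 at 969 ± 20.4 and 905 ± 31.0. Its adjusted p was 0.280 with quantile normalization, and its mean change was -0.05 with that setting and -0.03 with rescaling to a fixed sum. The collagen and fibrillar matrix list (35 tested, mean -0.06, adjusted p = 0.01005; adjusted p = 0.786 with an estimated correlation) fell by that test. It held Nid1 at 451 ± 16.8 and 394 ± 45.6, Fbn1 at 421 ± 38.7 and 375 ± 22.3 and Col14a1 at 504 ± 27.9 and 457 ± 47.5. It lost its call without cKO replicate 1 (adjusted p = 0.519), cKO replicate 4 (0.266) or control replicate 3 (0.0921), and with quantile normalization (0.823), array weights (0.136) or the epithelium covariate (0.302). Its mean change was -0.02 without cKO replicate 1, -0.04 without cKO replicate 4 and -0.10 without cKO replicate 3. With quantile normalization it was -0.02, with 16 of 35 members higher, and with rescaling to a fixed sum -0.03. The endoplasmic reticulum stress list (21 tested, mean -0.05, adjusted p = 0.0218; adjusted p = 0.560 with an estimated correlation) fell by that test. It held the chaperone gene Hspa5 at 1761 ± 89.0 and 1546 ± 86.3, Herpud1 at 142 ± 11.3 and 126 ± 2.95 and Xbp1 at 211 ± 7.50 and 195 ± 4.95. It lost its call without control replicate 2 (adjusted p = 0.1503), control replicate 4 (0.166) or cKO replicate 4 (0.269), and with quantile normalization (0.539) or rescaling to a fixed sum (0.0588). Its mean change was -0.03 without control replicate 2 or cKO replicate 4 and -0.09 without control replicate 3. With quantile normalization it was -0.03 and with rescaling to a fixed sum -0.02. In each of these 4 lists limma called 0 members over the list alone or over all genes, with 2, 1, 2 and 3 lower at an unadjusted p under 0.05.

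Epithelial transcripts, which the sort against EpCAM should remove, were measured in all libraries, with the highest list mean in cKO replicate 1. The epithelium list had a mean log2 value of 2.21 ± 0.459 in control and 3.27 ± 1.61 in cKO (SD, n = 4 each; exact permutation p = 0.314), with 5.17 in cKO replicate 1 and 3.92 in cKO replicate 2. All 18 tested members had a higher cKO mean, and the list rose by a mean of 1.06 (camera adjusted p = 2.8e-07; adjusted p = 0.560 with an estimated correlation). Without cKO replicate 1 the mean change was 0.42 and the adjusted p 0.0501, and without cKO replicate 4 the mean change was 1.63. The enterocyte gene Car1 had an FPKM of 21.7 ± 11.3 in control and 100.2 ± 85.3 in cKO, Guca2a 18.1 ± 9.51 and 114 ± 128, and the keratin gene Krt8 15.0 ± 4.15 and 58.0 ± 70.5. The antimicrobial lectins Reg3b and Reg3g had 4.91 ± 4.15 and 25.7 ± 19.8, and 1.91 ± 1.62 and 9.48 ± 9.17. The first principal component held 34.4% of the variance and placed cKO replicate 1 at 36.7, against -11.5 to 9.003 for the other libraries.

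The sort against CD45 should remove leukocytes. Myeloid markers rose by a mean of 0.22 (13 tested, camera adjusted p = 0.0340; adjusted p = 0.786 with an estimated correlation), and the call was lost without cKO replicate 1 (adjusted p = 0.966), control replicate 2 (0.123) or control replicate 3 (0.219). It was also lost with quantile normalization (0.0588), median-of-ratios scaling (0.0526), rescaling to a fixed sum (0.0811), array weights (0.367) and the epithelium covariate (0.658). Without cKO replicate 1 the mean change was -0.00035, so the rise came from that library. Fcer1g had 3.35 ± 0.676 and 7.48 ± 4.75, C1qc 3.59 ± 0.856 and 5.69 ± 2.06, Cd68 9.12 ± 1.77 and 7.37 ± 0.805, and the abundant markers Lyz2, Laptm5 and Tyrobp 37.7 ± 7.78 and 46.6 ± 20.1, 9.32 ± 1.49 and 11.5 ± 4.31, and 8.70 ± 3.90 and 10.8 ± 5.86. Lymphoid markers did not pass (10 tested, mean 0.16, adjusted p = 0.498), except without cKO replicate 3 (adjusted p = 4.0e-04). The list mean was 1.935 in that library, against 2.70 to 3.02 in the other cKO and 2.28 to 2.73 in the control libraries. The plasma cell genes Jchain and Mzb1 had 31.6 ± 14.9 and 60.8 ± 51.8, and 2.16 ± 1.15 and 5.23 ± 2.93, Cd79a 9.30 ± 1.12 and 8.62 ± 3.90, and Coro1a 8.04 ± 0.825 and 8.45 ± 3.24.

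Smooth muscle markers rose by a mean of 0.21, with all 10 tested members higher in the mean (camera adjusted p = 6.3e-04; adjusted p = 0.294 with an estimated correlation). The rise was not shared by all cKO libraries (two-sided exact permutation p = 0.143). The list mean was 2.79 in cKO replicate 2, below the 2.81 to 2.92 of the control libraries, and 3.09 to 3.23 in the other cKO libraries. Actg2, a smooth muscle actin, had 2.12 ± 0.450 and 3.41 ± 0.948, Cnn1 0.775 ± 0.249 and 1.31 ± 0.228, Synpo2 1.53 ± 0.198 and 1.89 ± 0.223, and the abundant Myl9, Acta2 and Tagln 119.6 ± 24.5 and 137 ± 21.4, 23.3 ± 1.01 and 30.6 ± 11.9, and 18.2 ± 0.933 and 22.6 ± 6.49. With a minimum mean FPKM of 5 the adjusted p was 0.0674. Blood endothelium markers rose by a mean of 0.41 (5 tested, adjusted p = 0.0171; adjusted p = 0.296 with an estimated correlation), and the call was lost without cKO replicate 1 (mean change 0.25, adjusted p = 0.0644) and with the epithelium covariate (0.111). Adjusted over the list alone 3 were higher and 1 lower, against 0 over all genes: Pecam1 (0.803 ± 0.178 and 1.54 ± 0.597), Plvap (3.57 ± 1.01 and 7.07 ± 4.04), Esam (0.812 ± 0.272 and 1.70 ± 0.858) and, lower, Tek (89.9 ± 3.19 and 80.2 ± 7.52). Kdr had 1.63 ± 0.643 and 2.76 ± 1.53.

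The sort against CD31, which Pecam1 encodes, should remove endothelial cells of blood and lymphatic vessels. Of the lymphatic endothelium markers, Ccl21a and Pecam1 passed the filter, too few for a list test. Both were higher adjusted over the list alone, but adjustment over 2 genes changes little. Over all genes 0 passed in limma (adjusted p = 0.761 for Ccl21a and 0.897 for Pecam1). Ccl21a, a chemokine that draws lymphocytes and dendritic cells to lymphatic vessels (chromosome 4, 42772860 to 42773993), was below 0.01 FPKM in control replicates 1, 2 and 4, at 4.49 in control replicate 3 and at 11.9, 4.81, 7.20 and 7.63 in cKO replicates 1 to 4. Gm1987, a gene on the same chromosome known as a copy of Ccl21, with 1134 bp against 1132 bp, showed the opposite distribution, with 3.25, 4.12 and 4.12 in control replicates 1, 2 and 4, 0.134 in control replicate 3 and 0.0992 to 0.137 in the cKO libraries. The sum of both was 4.03 ± 0.571 in control and 8.01 ± 2.99 in cKO (SD, n = 4 each; two-sided exact permutation p = 0.0286, the smallest possible). Without control replicate 3, limma called 3 genes, Mir5098, Gm1987 and Ccl21a (log2 difference 3.09, adjusted p = 0.00167). Whether the switch between the copies came from the assignment of shared fragments or from a difference in haplotype between the mice was not tested, so the values of Ccl21a and Gm1987 taken singly are uncertain.

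**Figure D3:**
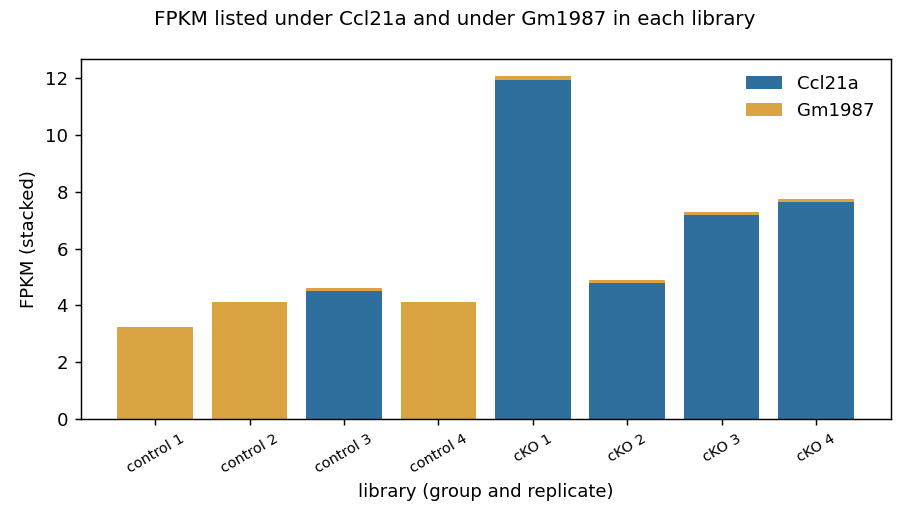
FPKM (vertical axis, stacked from 0) listed under Ccl21a and under its copy Gm1987 in each library (horizontal axis). Control replicates 1, 2 and 4 carry their FPKM of 3.25 to 4.12 under Gm1987, and the other libraries carry theirs under Ccl21a.

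Other cell types and functions did not pass as lists. Pericyte markers had a mean change of 0.06 (6 tested, camera adjusted p = 0.502). Pdgfrb was at 50.8 ± 2.16 and 53.0 ± 7.59, Cspg4 at 6.02 ± 0.587 and 6.57 ± 1.40, Abcc9 at 6.65 ± 1.07 and 6.41 ± 1.03 and Kcnj8 at 3.52 ± 1.24 and 3.80 ± 0.754. Mesothelium markers had 0.42 (3 tested, adjusted p = 0.502). Their list mean was 3.74 in cKO replicate 1, against 1.56 to 2.47 in the other cKO and 1.59 to 2.29 in the control libraries, so the rise came from that library. Krt19 was at 10.5 ± 2.99 and 35.6 ± 43.2, Wt1 at 2.67 ± 0.755 and 2.44 ± 0.783 and Krt7 at 0.740 ± 0.399 and 1.96 ± 2.43. Markers of interstitial cells of Cajal had a mean of 0.14 and a median of -0.06 (4 tested, camera direction higher, adjusted p = 0.992). The list mean was 3.48 in cKO replicate 1, against 2.64 to 2.89 in the other cKO and 2.58 to 3.08 in the control libraries. Gja1 was at 80.2 ± 15.3 and 75.9 ± 11.2, Etv1 at 4.23 ± 0.642 and 4.07 ± 0.610, Ano1 at 2.13 ± 0.396 and 1.84 ± 0.806 and Thbs4 at 0.991 ± 0.853 and 3.26 ± 3.85. Of the enteric glia list only Cryab passed the filter, at 137 ± 19.6 and 131 ± 16.997. The sorting markers had 0.30 (4 tested, adjusted p = 0.498). Pdpn was at 92.3 ± 1.82 and 88.7 ± 3.29 and Epcam at 3.58 ± 0.588 and 12.8 ± 15.3, of which cKO replicate 1 had 34.7.

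Complement genes had a mean change of 0.03, a median of -0.02 and a lower camera direction (15 tested, adjusted p = 0.998). C1qtnf1 was at 92.4 ± 4.64 and 84.5 ± 2.97, C2 at 9.14 ± 2.27 and 10.99 ± 1.09 and C5ar1 at 1.48 ± 0.274 and 2.22 ± 1.10. The TGF-beta and myofibroblast list had 0.03 (22 tested, adjusted p = 0.8289). Skil was at 31.3 ± 3.31 and 26.2 ± 2.95, Cyr61 at 1706 ± 57.2 and 1565 ± 122 and Id3 at 962 ± 40.0 and 911 ± 41.8. Of the alternatives, the list passed only without cKO replicate 2 (adjusted p = 0.0323). Its mean was 5.55 in that library, against 5.69 to 5.81 in the other cKO and 5.60 to 5.71 in the control libraries. The dissociation and immediate-early list had -0.03 (32 tested, adjusted p = 0.666). Atf3 was at 1174 ± 71.1 and 1055 ± 44.5, Ier3 at 274 ± 25.3 and 244 ± 17.6 and Myc at 176 ± 16.5 and 161 ± 8.16. Proliferation genes had -0.03 (21 tested, adjusted p = 0.474). Cenpa was at 2.94 ± 0.711 and 1.92 ± 0.186, Ccne1 at 5.38 ± 0.512 and 4.58 ± 0.362 and Pcna at 71.8 ± 3.72 and 67.1 ± 4.22. Glycolysis and hypoxia genes had -0.01 (23 tested, adjusted p = 0.992). Pfkl was at 5.28 ± 0.702 and 6.59 ± 0.791, Hk2 at 25.9 ± 3.16 and 20.0 ± 4.78 and Slc16a3 at 4.02 ± 0.457 and 5.55 ± 2.101. Oxidative phosphorylation genes had 0.00 (28 tested, adjusted p = 0.992). Ndufs3 was at 51.7 ± 1.39 and 46.2 ± 3.63, Uqcrfs1 at 42.0 ± 1.69 and 48.7 ± 6.66 and Ndufb5 at 53.7 ± 0.851 and 49.6 ± 3.00. The list passed without cKO replicate 1 (adjusted p = 0.00226) and with the epithelium covariate (0.00823). Its mean was 6.76 in cKO replicate 1, against 6.53 to 6.58 in the other cKO and 6.58 to 6.64 in the control libraries. Mitochondrially encoded transcripts were not analysed here.

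Gene by gene, limma called 1 of 11506 genes, the microRNA gene Mir5098, lower in cKO (adjusted p = 5.3e-05), and 0 higher. It was named after its values were seen. Mir5098 (chromosome 5, 77272757 to 77272838) lies within Rest (77265491 to 77286432), which itself had an FPKM of 6.82 ± 0.560 and 6.43 ± 0.435. The FPKM of Mir5098 was 143.9, 54.0, 45.9 and 45.8 in control replicates 1 to 4 and listed at 0 in all cKO libraries. With the median of the values above 0, scaled for depth, assumed to be 1 fragment, these stood for about 3, 1, 1 and 1 fragments against 0 (within 0.069 of whole numbers). At an unadjusted p under 0.05 limma gave 273 genes higher and 349 lower, 622 in all, where chance gives 575.3 for independent genes. Of the 35 divisions of the libraries into 4 and 4, 10 gave at least as many, with up to 932 in another division. The 4 cKO values did not overlap the 4 control values in 375 genes, 156 of them higher, against 328.7 by chance (2.86%).

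The genes with the smallest unadjusted p that were not called included, on the higher side, the lipid enzyme gene Lpcat4 (6.43 ± 0.589 FPKM in control and 9.18 ± 0.577 in cKO, log2 difference 0.45, SE 0.08, adjusted p = 0.570), Rasd1 (19.6 ± 1.74 and 24.7 ± 1.09) and Apip (16.2 ± 0.427 and 19.8 ± 1.54). The other 7 of the 10 were H2-T22, Ccl21a, Usp18, Igtp, B2m, H2-Q4 and Psmb9, of which 6 belong to the fixed interferon and antigen presentation lists. On the lower side stood Pcbd2 (42.0 ± 1.60 and 32.7 ± 2.15, log2 difference -0.35, SE 0.06, adjusted p = 0.570), the cyclin gene Ccny (10.7 ± 0.230 and 8.27 ± 0.433), Igsf1 (1.63 ± 0.301 and 0.660 ± 0.112), Taf13 (14.7 ± 0.396 and 12.0 ± 0.593), Islr2 (4.43 ± 0.557 and 3.08 ± 0.127), the glycogen phosphorylase gene Pygl (19.4 ± 0.748 and 15.8 ± 1.203) and Uap1 (234 ± 19.4 and 188 ± 16.1). The ribosomal genes Rps23 (724 ± 7.32 and 623 ± 39.6), Rpl36 (641 ± 7.75 and 536 ± 50.0) and Mrpl48 (43.2 ± 1.74 and 37.4 ± 1.73) completed the lower side.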

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

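Of the tests in this part, those of the epithelial carry-over, of the fragments behind Mir5098 and of cKO replicate 1 were chosen after the results were seen, and the test of linked regions after values of single genes had been seen. It took the place of a test of scaling between libraries, which had been run and had argued against scaling. A single library stood apart from the other 3 of its group in 6 of 110 groups examined, where chance gives 5.5. Control replicate 2 had a relative depth of 0.859, against 0.989 to 1.01 in the other control libraries. Igtp in control replicate 2 was at 12.8 FPKM, against 14.3 to 14.7. Pcbd2 in cKO replicate 3 was at 35.9, against 31.5 to 31.6, and Rpl36 in control replicate 1 at 629, against 643 to 646. Ccl21a in control replicate 3 was at 4.49, against values below 0.01, and its copy Gm1987 was low in the same library. Pdgfra in cKO replicate 1 was at 126, against 163 to 167.

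The 98 tested members of the type I, interferon-gamma and class I lists, pooled, were 0.24 higher in cKO (SE 0.08, log2 scale). Epithelial carry-over in cKO replicate 1 alone does not account for this, since the difference was 0.28 (SE 0.07) without that library. Its pooled mean (4.14) was the lowest of the cKO libraries, so leaving it out could only raise the difference. Carry-over in cKO replicate 2 (epithelium list mean 3.92), which had the highest pooled mean (4.42), was not tested on the pooled members. Without cKO replicate 2 the type I list was 0.13 higher, the interferon-gamma list 0.28 and the class I list 0.23. With the mean of the myeloid and lymphoid lists as a covariate the difference was 0.23 (SE 0.09), above a bound of 0.12. This argues against RNA from leukocytes, which the sort against CD45 should limit, but a margin of 1 SE is weak with 8 libraries. Variants in linked regions remain open: the 58 members outside chromosomes 5, 11 and 17, which hold the Pdgfra locus, a cluster of the GTPase genes and the major histocompatibility complex, were 0.18 higher (SE 0.07, exact permutation p = 0.0571), within 1 SE of the bound of 0.12 set for excluding this. Chromosome 5 was included on the assumption that the Cre allele lies at Pdgfra, which was not checked. The mean change was positive on all 19 chromosomes that hold members, but chromosomes 9, 10, 13 and 15 hold 1 member each, and chromosome 13 was at 0.0049. Since most pooled members were higher in cKO, these signs add little of their own. Loss of Il10ra from fibroblasts, the difference named by the design, stays among the open explanations, as do litter, housing or a difference in genetic background between the groups, none of which was tested.

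The FPKM of Mir5098, the 1 gene called over all genes, was read as about 6 fragments over the 8 libraries, all in control libraries. The values lay within 0.069 of whole numbers, for a tolerance of 0.1. This reading takes the median of the values above 0, scaled for depth (an FPKM of 46.4), as 1 fragment. That unit was not derived from the length of 82 bp and the estimated depth. By the plain FPKM formula these give a far lower value for 1 fragment, so the number of fragments is an assumption. Residual SDs were also wider for small RNA genes (median 1.64 against 0.127 for others). Chance in few fragments is a candidate explanation. If the unit holds, the exact binomial p for 6 against 0 fragments was 0.0127 from counting alone. A variant carried along on chromosome 5 with the Cre allele cannot be told apart from chance. That account assumes that the Cre allele lies at Pdgfra, which was not checked. Of 50 other tested genes within 10 Mb of Pdgfra, 2 had an unadjusted p under 0.05 (4.00%, 95% exact interval 0.488% to 13.7%) against 5.30% of genes elsewhere, one-sided Fisher exact p = 0.750. No biological explanation was tested for this gene.

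In cKO replicate 1 the epithelium list stood 2.54 above the other cKO libraries on the log2 scale. A lower share of fibroblasts in that library would raise all other cell types alike if their proportions to each other stayed the same, which was not tested. The highest of 5 other cell type lists, the myeloid one, stood 0.88 higher (SE 0.10), blood endothelium 0.63, lymphoid 0.43, smooth muscle 0.23 and pericyte -0.11. SEs here run over list members, which are not replicates. The endothelial, smooth muscle and pericyte lists weigh little, since Tek, Myl9 and Pdgfrb in them were abundant (89.9, 119.6 and 50.8 FPKM in control). On the assumption of constant proportions, the myeloid and lymphoid lists argue against a lower share as the whole cause. A lower share may still add to the pattern. Pdgfra was at 126 FPKM there, against 163 to 167 in the other cKO libraries. The collagen list differed by -0.14 (SE over members 0.03, 0 of 35 members highest there). The mesothelium list, left out of those 5, stood 1.72 higher (SE over members 0.84, 3 genes, among them the keratin genes Krt19 and Krt7, which epithelial cells also make). Carry-over of epithelial cells or their RNA, which the sort against EpCAM should limit, stays open, because the finding that 16 of the 18 tested members were highest in cKO replicate 1 restates the pattern. Goblet cell genes such as Clca1 (188 FPKM), Retnlb (32.4) and Fcgbp (28.0) and the enterocyte genes Car1 (152, and 191 in cKO replicate 2) and Guca2a (289) were measured there, and no biological explanation was tested.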

How the results depend on the processing

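The alternatives without small RNA genes, with the epithelium list mean as a covariate and with the exact permutation of list means were chosen after the data were seen. Leaving out the small RNA genes gave 0 changed genes, 0 of them lower, since Mir5098 was no longer tested. An unadjusted p under 0.05 with a 2-fold change gave 16 genes, 12 higher and 4 lower. With each library left out in turn the count was 1 to 4, with 0 to 3 higher (3 without cKO replicate 1) and 1 to 2 lower. The adjusted p of the type I list ran from 7.4e-18 to 9.2e-07 with a library left out and was 0.296 with an estimated correlation, 0.267 with fry and 0.286 with the exact permutation of list means. Its mean change, 0.18 over all libraries, was between 0.13 (without cKO replicate 2) and 0.22 (without cKO replicate 1) with a library left out. Of the other lists 12 passed, 0 with an estimated correlation, fry or the exact permutation, 7 with quantile normalization and 9 to 13 with a library left out. Each of those 3 tests gave 4 lists at an unadjusted p under 0.05, so the list calls rest on camera's preset correlation of 0.01, while the estimated correlation was 0.286 for the type I list and 0.694 for ribosomal proteins. The exact permutation could hardly pass after adjustment. Its smallest possible p of 0.0286 reaches the threshold over 30 lists only if most of them share it, so its lost calls decide nothing. The type I, interferon-gamma, class I and ribosomal lists each passed in 21 of 24 alternatives, with each library left out among them. For the losses with quantile normalization the cause was not tested. The epithelium and myeloid lists reversed with the epithelium covariate (adjusted p = 0.673 and 0.658), the former since the covariate is that list itself, while for the latter the cause was not tested. Scaling did not account for the pooled interferon change, which was 0.231 with quantile normalization, 0.242 with median-of-ratios scaling and 0.290 with rescaling to a fixed sum, against 0.236. For a gene or list called under neither setting, a change of sign was not counted as a reversal. The type I list shares 0 members with the other interferon lists, so the alternative without shared members was not run. Replicate numbers did not pair the libraries (correlations of deviations 0.0912, 0.0336, 0.0190 and 0.0182 for numbers 1 to 4, none matching its own number best), and with the number as a block the count stayed at 1, the other lists at 12 and the type I list at an adjusted p of 1.4e-11. Il10ra differed by -0.20 to -0.05 with a library left out, by -0.31 with a pseudocount of 0.1, by -0.25 with 0.25 and by -0.05 with the epithelium covariate, and was not called under any of these (adjusted p = 0.858 to 0.989 over its alternatives). At an estimated 17800000 fragments Il10ra rests on 17 to 51 fragments per library.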

Other observations

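The tests of lymphatic transcripts and the extra goblet, enterocyte and cholesterol lists were chosen after the values were seen. Values of the lymphatic endothelial markers below the filter follow. Flt4, the receptor of lymphatic growth factors, had 0.0764 ± 0.0505 FPKM in control and 0.227 ± 0.0368 in cKO, Mmrn1 0.303 ± 0.124 and 0.922 ± 0.359, and Lyve1 0.450 ± 0.346 and 0.811 ± 0.441 (SD, n = 4 each). Reln had 0.0304 ± 0.00907 and 0.0978 ± 0.0624, and Tie1 0.151 ± 0.0733 and 0.492 ± 0.379. Stab2 had 0.0388 ± 0.0391 and 0.0377 ± 0.0384, Cldn5 0.159 ± 0.164 and 0.160 ± 0.0874, and Prox1 0.232 ± 0.107 and 0.278 ± 0.0791. The hypothesis that the cKO libraries may hold more lymphatic endothelial RNA was tested on the mean log2(FPKM + 0.1) of 10 markers with Ccl21a and Gm1987 added. Ccl21a also stands in the fixed list of lamina propria fibroblast markers, so it does not mark lymphatic endothelium alone. The sort excluded CD31-positive cells, which should remove lymphatic endothelium, and Pecam1, the gene of CD31, was at 0.803 ± 0.178 and 1.54 ± 0.597 FPKM. The difference was 0.68 (two-sided exact permutation p = 0.0571), which leaves it open. The test was first run with Ccl21a alone, where the difference was 1.07 (exact p = 0.0286), and was changed to the sum once the copy had been found. Assignment of shared fragments and a haplotype that differs between the mice are both open for the switch between the copies, and the latter would bear on whether the groups shared 1 genetic background. Neither was tested. Without either copy the difference was 0.65 (exact p = 0.0571), and without Pecam1, Cldn5 and Tie1 as well 0.64 (exact p = 0.0286). Without cKO replicate 1 the difference was 0.49 (exact p = 0.0857).

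Transcripts of the interferon genes Ifnb1 and Ifng were near the floor. Ifnb1 was at 0.102 ± 0.118 FPKM in control and 0.0232 ± 0.0464 in cKO, and Ifng at 0.0264 ± 0.0529 and 0.0501 ± 0.0698 (SD, n = 4 each). The chemokine gene Cxcl9 had 0.273 ± 0.136 and 0.449 ± 0.171, and Cxcl10 119 ± 20.4 and 119 ± 4.94. The interferon-gamma list changed more in the mean than the type I list (0.31 and 0.18, but 0.25 and 0.18 without cKO replicate 4). The hypothesis that interferon-gamma acts more than type I interferon was tested on the difference between the list means per library, 0.346 ± 0.0430 in control and 0.475 ± 0.124 in cKO (difference 0.13, two-sided exact permutation p = 0.0857). The bound set beforehand for excluding it was a p of 0.05 or more, which was the wrong bound, since a p that misses the threshold does not show that the lists changed alike. Whether members of the interferon-gamma list also respond to type I interferon, or the reverse, was not tested. The difference between the list means therefore cannot separate these interferons, whatever its p. The hypothesis may hold or not.

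Goblet cell genes had a list mean of 1.88 ± 0.425 in control and 3.06 ± 2.05 in cKO, with 5.85 in cKO replicate 1, and enterocyte genes 2.25 ± 0.474 and 3.38 ± 1.51, with 4.99 in cKO replicate 1 (exact permutation p = 0.371 and 0.257, SD, n = 4 each). A cholesterol synthesis list of 20 genes had 3.52 ± 0.229 and 3.70 ± 0.266 (exact permutation p = 0.371). The small RNA gene AF357425 was listed at 0 in all control libraries and in cKO replicate 2, and at 78.1, 75.02 and 81.2 in cKO replicates 1, 3 and 4, and without cKO replicate 2 limma called 2 genes, AF357425 and Mir5098. In all, 15 genes were listed at 0 in 1 whole group and above 0 in all 4 libraries of the other, and 9 of the 35 divisions of the libraries gave as many, with a highest other value of 18.

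All 35 divisions of the 8 libraries into 4 and 4 were tested. As many genes as the real 1 were called in 8 of the 35, with a highest other count of 2, so chance is not excluded for the gene count. Nor is it for the 622 genes at an unadjusted p under 0.05, which 10 of the 35 divisions reached, with up to 932. For 3 lists the real division gave the smallest camera p: class I (1 of 35 divisions with a p as small, the real one at 4.5e-14 and the smallest other at 2.0e-11), adventitial markers (1 of 35, 6.4e-06 and 6.6e-06, nearly equal) and ribosomal proteins (1 of 35, 4.7e-19 and 1.4e-16). That rank is the best possible and was read for 13 lists chosen because they passed. Chance is therefore not excluded for them over the lists tested. The exact permutation p of each of these 3 lists was 0.214 after adjustment over the lists, but that test could hardly pass with 4 against 4 libraries and decides nothing here. Nor was chance excluded for the type I list (2 of 35, 6.1e-14 and 1.1e-18) or the interferon-gamma list (3 of 35, 4.3e-12 and 3.2e-14). The same holds for smooth muscle (5 of 35, 1.5e-04 and 3.1e-06), blood endothelium (3 of 35, 0.00626 and 0.00445), epithelium (14 of 35, 4.6e-08 and 6.5e-19), myeloid markers (21 of 35, 0.0147 and 1.1e-07), NF-kB genes (8 of 35, 3.1e-04 and 1.9e-10), collagens (13 of 35, 0.00335 and 3.0e-10), matrix proteases (5 of 35, 7.9e-04 and 6.8e-06) and endoplasmic reticulum stress genes (7 of 35, 0.00873 and 3.1e-06). Other divisions passed a median of 7 and up to 14 lists, against 13 in the real one.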
